A study of Rattus norvegicus with 3 samples.

How the data were processed

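Total RNA from thoracic aorta of Sprague Dawley rats was measured on 3 oligonucleotide arrays, 1 for each of 3 groups dosed for 20 days with water at 1 ml/kg (control), allylamine at 35 mg/kg or allylamine at 70 mg/kg, per the labels. The labels speak of rats in each group, and whether an array carried RNA of 1 animal or of a pool is not given in the sources used here. The deposited table holds 1 intensity per probe set and array on a linear scale. The software and the scaling that the authors used to make these intensities are not given in the sources used here. The deposited values were all positive, and after trimming 2% of the probe sets at each end their mean was 500.4 on the control array, 500.4 on the 35 mg/kg array and 500.2 on the 70 mg/kg array, so the values had already been scaled to a common mean. The deposited medians were 256 on the control array, 260 on the 35 mg/kg array and 284 on the 70 mg/kg array.

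Of the 8799 probe sets in the table, 59 control probe sets were left out of the comparisons and 8740 were kept. The platform annotation gave exactly 1 gene symbol to 7006 of these, several to 308 and none to 1426. Only probe sets with 1 symbol were named. Of these, 6985 were found by gene ID in the gene table of the GRCr8 rat assembly, which changed 0 symbols, and the others kept the platform's name. The 7006 probe sets stood for 4736 genes, 1565 of them with more than 1 probe set. No probe set carried the symbol of the vascular amine oxidase Aoc3 alone, and this gene was not analysed here.

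Each array was scaled linearly so that its median over the 8740 probe sets equalled the mean of the 3 medians, which shifted the arrays by 0.06 (control), 0.04 (35 mg/kg) and -0.09 (70 mg/kg) on the log2 scale. A floor was set at the 40th percentile of all scaled values, an intensity of 188, values below it were raised to it, and log2 was taken. A probe set entered a comparison when it lay above the floor on both arrays. A gene's difference was the median of the log2 differences of its measured probe sets, and a gene was counted as higher or lower when that median was at least 2-fold, a log2 difference of 1. Genes above the floor on 1 array only and at least 2-fold above it there were counted apart as bounds. With 1 array per group there was no test between groups and no p-value, and the number of arrays limits the precision of every difference.

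The spread between probe sets of one gene was the only repeat measurement within an array. It was described by its SD, by the share of pairs with the same sign and by the correlation of their log2 differences across genes, set beside 1000 random pairings matched on intensity. Genes are not independent replicates, so these correlations describe the arrays and not the animals. Gene lists, 24 for pathways and 14 for cell types, were described by the median difference of their measured genes and its percentile among 10000 random lists of the same size matched on mean log2 value in 20 bins. A list of at least 5 measured genes was said to stand apart below the 2.5th or above the 97.5th percentile, as a description of these arrays. Because both doses were compared with the same control array, their agreement was set beside 1000 simulated sets of 3 unchanged arrays. The error in these was drawn by intensity decile from the differences between the 70 and 35 mg/kg arrays.

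Genes were named by a rule fixed before the data were examined, as were the lists, the groups and the main settings. The rule took the 14 genes with the largest increase and the 14 with the largest decrease at 70 mg/kg, 8 and 8 at 35 mg/kg, and 5 and 5 between the doses, where all measured probe sets had the same sign and the symbol was not a placeholder. It also took up to 4 members of each described list with the largest absolute differences, and which lists that did not stand apart have their members named was chosen after the values had been seen. The rule further took 12 genes fixed for their part in allylamine metabolism, oxidative response or the arterial wall, and the 5 largest bounds each way at 70 mg/kg.

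The calculation was tested on simulated data made from the real mean values of 4736 genes, with 200 genes changed in the 70 mg/kg array. With an error SD of 0.20 per array, 96% to 100% of the changed genes passed the 2-fold rule, and 0.0351% of 2850 unchanged genes did. With an error as large as that between probe sets of one gene in the comparison of 70 mg/kg with control (SD 0.99 per array), 68% of 50 genes raised by 2.00 passed, as did 38% of 50 genes with a change of -2.00, 54% of 50 genes raised by 1.50 and 50% of 50 genes with a change of -1.50. At this error 37.2% of 2429 unchanged genes passed, and a list of 20 genes raised by 1.00 lay at the 99.65th percentile.

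Alternatives fixed in advance were the values as deposited, quantile normalization, scaling to a common 2% trimmed mean, floors at the 5th, 25th and 55th percentile, the brightest probe set per gene, each probe set by itself and a 3-fold rule. Floors at the 65th, 75th and 85th percentile, the removal of probe sets marked as less specific by their names, and pairs of probe sets from different sequence accessions only, at each floor, were added after the data had been seen. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.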

Results

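The arrays measured transcripts of the thoracic aorta of Sprague Dawley rats after 20 days of dosing. There were 3 groups with 1 array each: water at 1 ml/kg, allylamine at 35 mg/kg and allylamine at 70 mg/kg. Allylamine is an unsaturated amine that injures heart and arteries, and the semicarbazide-sensitive amine oxidase of vascular smooth muscle converts it to the reactive aldehyde acrolein and hydrogen peroxide. The series asked how the aorta responds to the dose. Because every group had 1 array, no difference reported here has a replicate check, and values are given as log2 differences without an error between animals.

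The arrays resembled one another only in part. Across probe sets, which are not independent replicates, log2 values correlated with r = 0.70 between control and 35 mg/kg, 0.59 between the doses and 0.48 between control and 70 mg/kg. The 5' and 3' probe sets of cytoskeletal actin gave a 3' over 5' ratio of 0.376 on the control array, 0.542 at 35 mg/kg and 1.42 at 70 mg/kg, and those of the glycolytic enzyme GAPDH gave 0.175, 0.318 and 0.226. The 3' GAPDH probe set was dim on every array, at deposited intensities of 218, 282 and 250. These lay near the array medians of 256, 260 and 284, so the GAPDH ratio rests on a weak signal. The hexokinase control probe sets lay below the floor on every array, and their ratio is not given. Probe sets for the bacterial and phage control transcripts, which are added already labelled to the hybridisation mix, were a median of 3.81 times as bright at 35 mg/kg and 28.8 times as bright at 70 mg/kg as on the control array. The 95th percentile of the aortic probe sets lay above the 5th by 6.58 on the log2 scale on the control array, 6.16 at 35 mg/kg and 5.22 at 70 mg/kg.

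**Figure D1:**
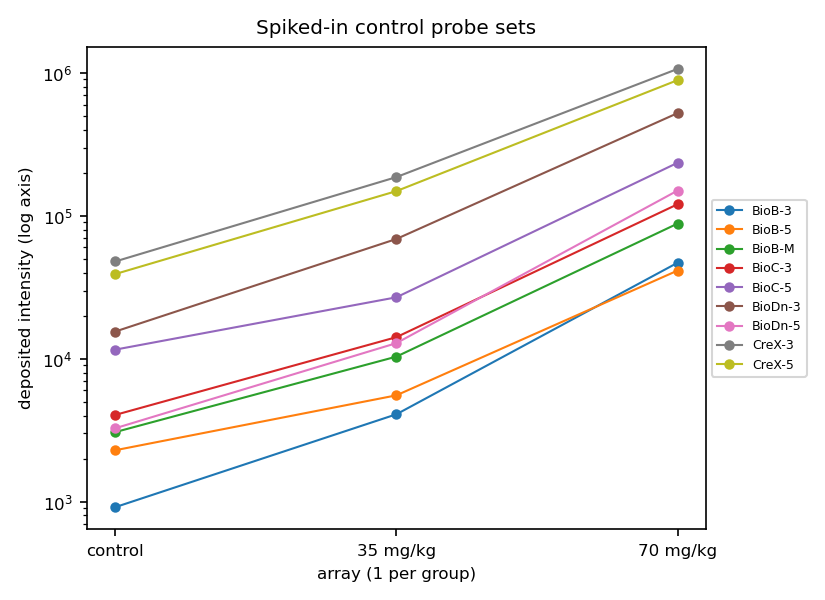
Deposited intensity (log axis) of the 9 spiked-in control probe sets on each of the 3 arrays, with 1 line per probe set. The probe sets were 18.1 to 51.3 times as bright at 70 mg/kg as on the control array, and 2.32 to 4.47 times as bright at 35 mg/kg.

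At 70 mg/kg, the type I collagen chain Col1a1 was higher than in the control aorta by 1.05, with all 4 of its probe sets higher (0.33 to 4.70). Of these, 2 come from the same sequence accession and may share probes. The adhesive glycoprotein fibronectin (Fn1) was higher by 1.58 on 2 measured probe sets (1.37 to 1.79), while another went from 359.6 to 142, below the floor. The 2 measured Fn1 probe sets come from the same sequence accession and may share probes. Elastin (Eln), the main elastic fibre protein, differed by 0.91. Lysyl oxidase (Lox), which crosslinks collagen and elastin, differed by 0.51 on 1 probe set, and another went the other way, from an intensity of 672 to 179, below the floor; with the values as deposited the Lox difference was -0.55. Of the electrophile response genes, the quinone reductase Nqo1 was higher by 1.84 on 1 probe set, its other lying below the floor on all 3 arrays. Heme oxygenase Hmox1 differed by -1.27. Gsta4, the glutathione transferase that conjugates the lipid aldehyde 4-hydroxynonenal, differed by 0.19 on 1 probe set, and its other probe set went from an intensity of 187, just below the floor, to 1545. The smooth muscle actin Acta2 differed by -0.02, with its 2 measured probe sets at -0.73 and 0.69, and by 0.13 with the values as deposited. Another Acta2 probe set went from 112, below the floor, to 267. The smooth muscle myosin Myh11 differed by -0.29 on 1 probe set, and another went from 123, below the floor, to 426. Osteopontin (Spp1) lay below the floor on all 3 arrays, and Gclc, the catalytic subunit of glutathione synthesis, lay above it on the control array only.

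**Figure D2:**
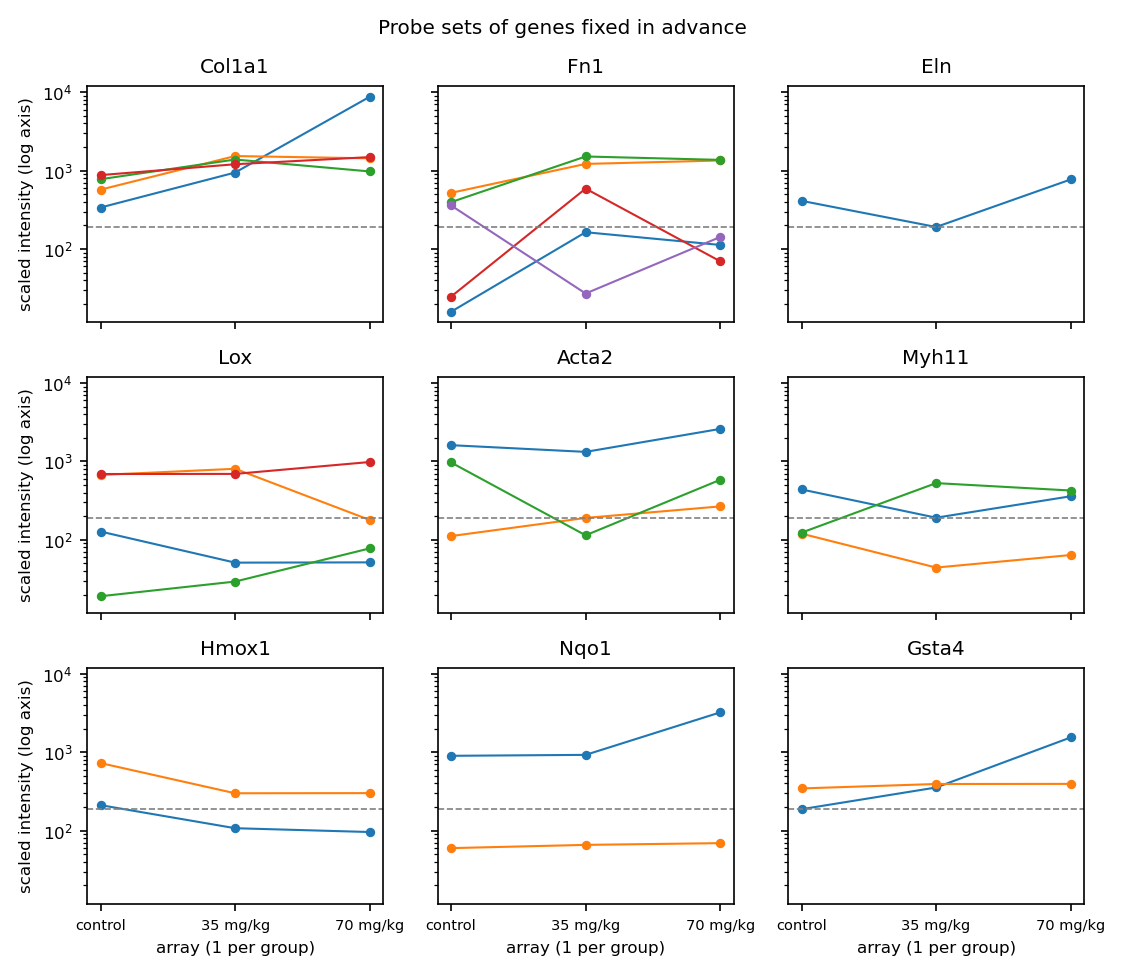
Scaled intensity (log axis) of each probe set of 9 genes fixed in advance, on the control, 35 mg/kg and 70 mg/kg arrays, with 1 line per probe set and the floor of 188 dashed. The 4 Col1a1 probe sets lay higher at both doses than on the control array, while the probe sets of Fn1, Acta2 and Myh11 did not all run the same way.

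Of 2462 genes measured on both arrays, 486 were at least 2-fold higher at 70 mg/kg and 571 at least 2-fold lower, together 42.9%. Those higher were 46.0% of the 2-fold differences, but 51.1% with the values as deposited. A further 380 genes lay above the floor only at 70 mg/kg and 384 only in the control by at least 2-fold. The largest increase was that of Oaz2, an antizyme that restrains polyamine synthesis, at 5.04. It was followed by the fatty acid hydroxylase Cyp4a3 (3.97), the mitochondrially encoded oxidase subunit COX3 (3.71), the ciliary neurotrophic factor receptor Cntfr (3.64) and the thyrotropin-releasing hormone receptor Trhr (3.58). The electron donor cytochrome b5 (Cyb5a) was higher by 3.48 on 2 probe sets (3.33 to 3.63), and the mitochondrial manganese superoxide dismutase Sod2 by 3.46. The DNA end-joining factor Paxx (3.37), the kinase Camkk2 (3.30), the calcineurin inhibitor Cabin1 (3.27), the transcription factor Hlf (3.20), Grina (3.13), the nicotinic receptor subunit Chrna4 (3.10) and the hepatic cytochrome P450 Cyp2c13 (3.0) completed the increases named. With a floor at the 5th percentile, which lets in further probe sets, Hlf was at -0.89 and Cyp2c13 at -0.0087.

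The largest decrease at 70 mg/kg was that of the class I histocompatibility gene RT1-S3, at -4.81, and another class I gene, RT1-CE16, differed by -4.00. The mitochondrial thioredoxin Txn2 differed by -4.70, from an intensity of 17209 to 662, and the brain-type creatine kinase Ckb by -4.19, from 16834 to 922. The Notch feedback gene Nrarp was lower, at -4.28, as were the adenylyl cyclase Adcy5 at -4.18, the p53 ubiquitin ligase Mdm2 at -4.15 and the myosin regulatory light chain Myl12a at -3.66. Arl6ip4 (-4.37), Tmem255b (-4.19), Tmem79 (-4.17), the synaptic scaffold gene Shank2 (-3.99), the insulin gene Ins2 (-3.90) and Prxl2c (-3.64) were also among the 14 largest decreases. Of genes above the floor on 1 array only, Eif4h was at least 12.4-fold higher at 70 mg/kg, Dusp6, a phosphatase of ERK kinases, at least 11.3-fold, Myo9a at least 11.1-fold, Cep78 at least 11-fold and Rab1a at least 9.79-fold. Those lower were Sult5a1, by at least 58.5-fold, the nuclear receptor coactivator Ncoa1, by at least 34.2-fold, Gtf2ird1, by at least 25.1-fold, the Wnt pathway scaffold Axin1, by at least 23.3-fold, and Tmem101, by at least 19.9-fold.

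Among the gene lists at 70 mg/kg, fatty acid oxidation and ketone metabolism had the lowest median, -1.03, at the 0.09th percentile of random lists. Of its 19 measured genes 10 were at least 2-fold lower and 2 at least 2-fold higher. The enoyl-CoA isomerase Eci1 differed by -3.39, the muscle carnitine palmitoyltransferase Cpt1b by -2.98, the trifunctional protein subunit Hadha by -2.32 (3 probe sets, -4.24 to 0.96) and the hydroxyacyl-CoA dehydrogenase Hadh by -2.25. Sterol synthesis and cholesterol uptake had the highest median, 1.04, at the 98.3rd percentile, with 5 of 10 measured genes at least 2-fold higher and 0 lower. These included the lanosterol demethylase Cyp51 (2.30), Dhcr7, which makes cholesterol from its last precursor (2.08), the mevalonate kinase Mvk (1.64) and Acat2 (1.47, but -0.39 with a floor at the 5th percentile). Cytosolic ribosomal proteins had a median of 0.56, at the 98.5th percentile, with 8 of 23 genes at least 2-fold higher and 1 lower, among them Rpl19 (2.92), Rps29 (2.83, with 2 probe sets at 0.47 and 5.20), Rps9 (2.20) and Rplp0 (-2.25). Above a floor at the 55th percentile the fatty acid oxidation median was 0.00 over 9 genes (53.9th percentile), after quantile normalization it was -0.60 (3.07th percentile), and with the values as deposited the sterol and ribosomal medians of 0.77 and 0.59 lay at the 92.6th and 97.2nd percentile. The sterol median was 0.59 (90.4th percentile) and 0.52 (82.3rd percentile) with floors at the 25th and 5th percentile, and the ribosomal median was 0.33 (90.1st percentile) without less specific probe sets and 0.32 (92.1st percentile) above the 75th percentile floor, both chosen after the data had been seen. The 70 mg/kg array was also the one with the brightest spike-ins and the narrowest range, as given above.

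Lists tied to the arterial wall and to allylamine's products lay within the random range at 70 mg/kg. Contractile smooth muscle genes had a median of -0.27 (27.2nd percentile), with 3 of 11 at least 2-fold higher and 2 lower. Calponin (Cnn1) was at 2.86, phospholamban (Pln), a regulator of the calcium pump, at 2.36, the potassium channel subunit Kcnmb1 at -1.66 and tropomyosin Tpm1 at -3.35, although its 3 probe sets ran from -3.63 to 6.09. Collagens and structural matrix had a median of 0.33 (91.7th percentile), with 7 of 21 genes at least 2-fold higher and 5 lower, the latter including the laminin chain Lamc1 (-2.54), biglycan (Bgn, -2.30), Col5a1 (-2.04) and Col10a1 (-1.75). Glutathione and electrophile response genes divided evenly, 7 of 16 higher and 7 lower, with Gstm2 (2.88) and Gstm1 (1.94, 3 probe sets at 0.26 to 3.40) above and the glutathione synthetase Gss (-3.63) and Mgst2 (-1.99) below. The median of this list was -0.14 (46.2nd percentile). Amine and aldehyde metabolism had a median of -0.36 (25th percentile), with 1 of 13 genes higher and 2 lower. The aldehyde dehydrogenase Aldh7a1 was at 1.06 on 2 probe sets (1.03 to 1.09), the mitochondrial aldehyde dehydrogenase Aldh2 at -0.89, the formaldehyde-clearing dehydrogenase Adh5 at -1.51 and the carbonyl reductase Cbr1 at -1.59, but 0.32 with a floor at the 25th percentile.

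Antioxidant enzymes had a median of -0.14 at 70 mg/kg (41.5th percentile), which was above 0 with the values as deposited (0.01), after quantile normalization (0.09) and with a common trimmed mean (0.02). Beside Sod2 and Txn2, the selenoprotein Selenow was at 1.49 and the glutathione peroxidase Gpx2 at -2.01. Heat shock and ER stress genes had a median of 0.43 (90.4th percentile), with 4 of 16 at least 2-fold higher and 1 lower, and the chaperones Hspa5 (1.78), Pdia4 (1.56), Hspb6 (1.39) and Hspa1a (1.23) were above control. Mitochondrial respiratory chain and TCA cycle genes had a median of 0.15 (77.6th percentile), with 6 of 23 higher and 7 lower. The complex I subunits Ndufa9 (2.88) and Ndufs1 (2.75) lay above control, and the ATP synthase subunit Atp5f1d (-2.27) and citrate synthase (Cs, -2.17) below it.

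**Figure D3:**
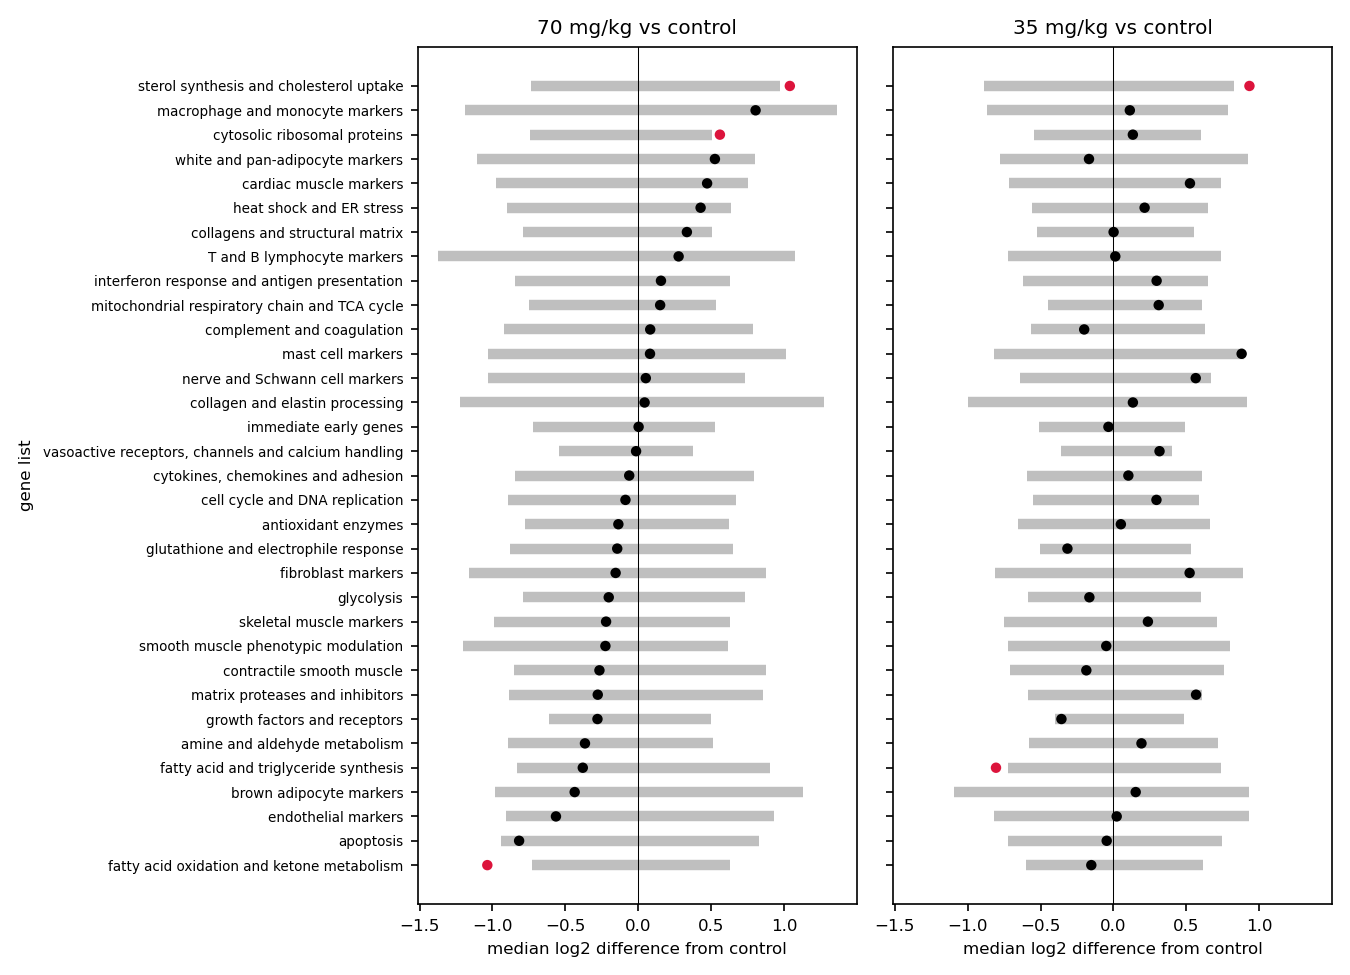
Median log2 difference from control (horizontal axis) of each gene list with at least 5 measured genes at 70 mg/kg (vertical axis), at 70 mg/kg and at 35 mg/kg. Grey bars span the central 95% of 10000 random lists matched on intensity and red points lie outside them. Sterol synthesis lay above the bar at both doses (1.04 and 0.93), which share the control array, and fatty acid oxidation below it at 70 mg/kg (-1.03). The integrin list, with 4 measured genes at 70 mg/kg, is not drawn.

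At 35 mg/kg, Col1a1 was higher than control by 1.13 on all 4 probe sets (0.46 to 1.48) and Fn1 by 1.58 on the 2 from the same sequence accession (1.23 to 1.94), while 2 further Fn1 probe sets crossed the floor in opposite directions. Decorin (Dcn), a proteoglycan that binds collagen fibrils, was higher by 2.65 on 3 probe sets (1.57 to 2.68), and the matrix glycoprotein tenascin C (Tnc) by 1.41. Eln differed by -1.11, Lox by 0.13 and Acta2 by -0.28 on 1 probe set. Another Acta2 probe set went from 970 to 114, below the floor, and the last from 112, below the floor, to 190. Myh11 differed by -1.20 on 1 probe set, which at 35 mg/kg also lay at 191. Another went from 123, below the floor, to 529. Hmox1 differed by -1.28, Nqo1 by 0.04 and Gsta4 by 0.19, with its other probe set going from 187 to 355. The copper-zinc superoxide dismutase Sod1 was higher by 1.60 on 2 probe sets (1.58 to 1.62), and Sod2 by 2.16.

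Of 2606 genes measured on both arrays, 439 were at least 2-fold higher at 35 mg/kg and 424 at least 2-fold lower, together 33.1%, with 211 and 264 more as bounds. The dynein light chain Dynlrb1 had the largest increase, 4.04, followed by the membrane raft protein Flot2 (3.54), Trhr (3.49), coagulation factor X (F10, 3.43), the transcription factor Gata3 (3.36), the myelin gene Mobp (3.31), atrial natriuretic peptide (Nppa, 3.18) and the somatostatin receptor Sstr4 (3.04). The egg coat gene Zp1 had the largest decrease, -4.43. It was followed by Pea15 (-3.43), Ncoa1 (-3.31), the peptidylarginine deiminase Padi2 (-3.29), Lrba (-3.12), the endothelial adhesion ligand Glycam1 (-3.11), Ncdn (-3.05) and the mitochondrial ribosomal gene Mrpl52 (-3.01).

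Sterol synthesis and cholesterol uptake stood above random lists at 35 mg/kg too, with a median of 0.93 (98.4th percentile) and 4 of 8 genes at least 2-fold higher: Cyp51 (2.13), Dhcr7 (1.89), the lanosterol synthase Lss (1.56) and the squalene synthase Fdft1 (1.01). Both doses were compared with the same control array, so the sterol medians at the doses are not independent. The list's level lay at the 3.39th percentile of random lists on the control array. It lay at the 28.8th at 35 mg/kg and the 57.9th at 70 mg/kg. Between the doses the sterol median was 0.10 (53.3rd percentile). Fatty acid and triglyceride synthesis had a median of -0.81 (1.5th percentile), with 4 of 11 genes lower and 0 higher. Those were the lipogenic regulator Srebf1 (-1.56), the glycerol phosphate dehydrogenase Gpd1 (-1.12), the acyltransferase Gpam (-1.06) and the glucose transporter Slc2a4 (-1.0, with 2 probe sets at -3.38 and 1.38). Integrins and focal adhesion had a median of -0.69 (2.32nd percentile), with 3 of 9 genes lower, the integrin chains Itgb4 (-1.91) and Itga8 (-1.39) and the linker talin (Tln1, -1.08), while Itgav was at 0.90. With the brightest probe set per gene the fatty acid synthesis median was -0.25 (25.1st percentile) and the sterol median lay at the 97.3rd percentile. The fatty acid synthesis list stood apart in 3 of 8 alternatives. With floors at the 5th, 25th and 55th percentile its median was -0.33 (21.7th percentile), -0.47 (7.83rd) and -0.61 (14.1st). After quantile normalization it was -0.76 (2.7th percentile). With floors at the 25th and 5th percentile the sterol median was 0.58 (93.2nd percentile) and 0.18 (74.5th percentile), and with the latter Lss was at -0.91, Gpam at 1.09 and Nppa at -0.29. The integrin list lay inside the random range in all 7 alternatives that left it at least 5 genes. On the 35 mg/kg array the spike-ins were brighter than on the control array (3.81-fold) and the GAPDH ratio was the highest of the 3 arrays (0.318 against 0.175). The 3' GAPDH probe set behind this ratio was dim on every array.

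The contractile list had a median of -0.19 at 35 mg/kg (28.5th percentile), with 1 of 12 genes higher and 4 lower, Cnn1 being at 1.54, Tpm1 at -1.28 (3 probe sets, -1.44 to 4.53) and Itga8 and Myh11 as given above. Collagens and structural matrix had a median of 0.00 (49.0th percentile), with 4 of 20 genes higher and 6 lower, Col15a1 being at -1.55. Glutathione and electrophile response genes had a median of -0.32 (11.4th percentile), with 2 of 20 higher and 4 lower, among them Gstk1 (2.08), Gstm2 (1.78), Gss (-1.88) and Mgst2 (-1.5). Antioxidant enzymes had a median of 0.05 (49.5th percentile), with Gpx2 at -2.21 and the peroxiredoxin Prdx2 at 1.46.

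Between the doses, Nqo1 was higher at 70 than at 35 mg/kg by 1.80 and Eln by 2.02, while Hmox1 (0.01), Fn1 (0.00) and Col1a1 (0.10, 4 probe sets from -0.51 to 3.21) had similar values. Gsta4 was higher by 1.06, with its 2 probe sets at 0.01 and 2.12. Of 2459 genes, 355 were at least 2-fold higher at 70 mg/kg and 514 at least 2-fold lower, with 361 and 324 more as bounds. Those higher were 40.9% of the 2-fold differences, and 48.5% with the values as deposited, so the split depends on the scaling. The complex I subunit Ndufa8 (3.84), Oaz2 (3.77), the platelet-activating factor receptor Ptafr (3.0), Paxx (2.96) and Ralgapa1 (2.93) were the largest increases. Tmem255b (-4.68), the prolyl isomerase Fkbp2 (-4.65), Txn2 (-4.12), Ckb (-4.08) and Arl6ip4 (-3.95) were the largest decreases. Each of these increases and decreases rested on 1 measured probe set.

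Cytosolic ribosomal proteins stood above random lists between the doses, with a median of 0.53 (99.75th percentile), 5 of 21 genes higher and 1 lower. Rps29 (2.14, 2 probe sets at 0.20 and 4.09), Rpl35 (1.74), Rpl31 (1.71) and Rps3a (1.48) led the list, whose median after quantile normalization was 0.49 (97.2nd percentile), and the 70 mg/kg array was the one with the brightest spike-ins, the narrowest range and the highest actin ratio. Macrophage and monocyte markers had a median of 1.07 over 5 genes (97.7th percentile), 3 of them at least 2-fold higher: the leukocyte phosphatase Ptprc (1.48), the endotoxin receptor Cd14 (1.21, 2 probe sets at -0.05 and 2.48) and the Fc receptor Fcgr2b (1.07), with Cd74 at -0.88. Glutathione and electrophile response genes had a median of 0.39 (95.8th percentile), with Gstm1 at 2.09 (3 probe sets, -0.55 to 2.78), Ggt5 at 1.78 and Gstm7 at -1.84. With a floor at the 25th percentile, which left 9 macrophage genes, their median was -0.54 (18.3rd percentile), and with the brightest probe set per gene it was -0.047 (46.2nd percentile). In the collagen list, whose median was 0.00 with the main scaling and -0.21 with the values as deposited, Bgn was at -2.62 on 2 probe sets (-3.21 to -2.04), Lamc1 at -2.31 and Dcn at -1.94. Lists standing apart numbered 3 of 33 at 70 mg/kg, 3 of 34 at 35 mg/kg and 2 of 32 between the doses, where 5% of lists would give 1.65, 1.7 and 1.6.

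The doses were compared gene by gene against the control they share. Over 2122 genes measured on all 3 arrays their differences from control correlated with r = 0.57, against 0.50 (0.46 to 0.53) in simulated unchanged arrays, and their covariance was 0.81 against 0.60, a difference of 0.21. Genes at least 2-fold higher at both doses numbered 191, against 161 (137 to 186) simulated and 77.9 for independent lists, and genes lower at both numbered 206, against 145 (122 to 168) and 82.6. The 35 mg/kg value lay between control and 70 mg/kg for 586 of the 944 genes that were at least 2-fold from control at 70 mg/kg, or 62.1%, against 57.4% (53.7% to 61.1%) simulated. Trhr, Cntfr and Cyb5a were among those higher at both doses. The single control array cannot be split, so part or all of the excess may come from that array. The simulation assumes equal error on all 3 arrays. At 70 mg/kg, however, 944 genes were at least 2-fold from control, against 726 (687 to 770) simulated. Unequal error between arrays could change the expected overlap and the expected share between, and this was not simulated.

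Different probe sets of one gene seldom gave the same difference. At 70 mg/kg the log2 differences of 730 pairs of probe sets of 490 genes correlated with r = 0.0557, within the central 95% of random pairings (-0.0653 to 0.0757), and 52.9% of pairs shared a sign. At 35 mg/kg the 832 pairs of 562 genes gave r = 0.0879, above the random range (-0.0650 to 0.0656), with 54.6% sharing a sign, and between the doses r was 0.0591 (-0.0642 to 0.0737). The SD between probe sets of one gene was 1.40 at 70 mg/kg, 1.08 at 35 mg/kg and 1.22 between the doses, each larger than the 2-fold rule. Pairs from different accessions, separated after the data had been seen, gave r = 0.0254 at 70 mg/kg and 0.0341 at 35 mg/kg, within the random range, and 0.0816 between the doses, just above it (-0.0742 to 0.0787). Over 7 floors such pairs lay above random at 4 for 70 mg/kg, 0 for 35 mg/kg and 2 between the doses. The floors are nested, so these counts are not of separate checks. At 70 mg/kg the 25th percentile floor was nearly tied with its bound (r = 0.0536 against 0.0535). The floors at the 75th and 85th percentile rested on 55 and 23 pairs. Of 348 genes with probe sets from different accessions, 33 had all of them at least 2-fold the same way at 70 mg/kg, against 30.2 (21 to 40) in random pairings, and at 35 mg/kg 18 of 387 did, against 19.5 (12 to 29). The sets shared 5 genes, against 4.23 (1 to 8) when probe sets were shuffled with both differences from the shared control kept together, a test chosen after the data had been seen. Of these 5, identified after their values had been seen, Cyb5a, the fucosyltransferase Fut1 and Sod1 were higher at both doses, and the kinase Csnk1d and the RNA-binding protein Ssb lower. Sod1 was at 1.05 and 1.60, Fut1 at 2.49 and 1.51, Csnk1d at -2.32 and -1.97, and Ssb at -2.67 and -1.89, at 70 and 35 mg/kg.

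**Figure D4:**
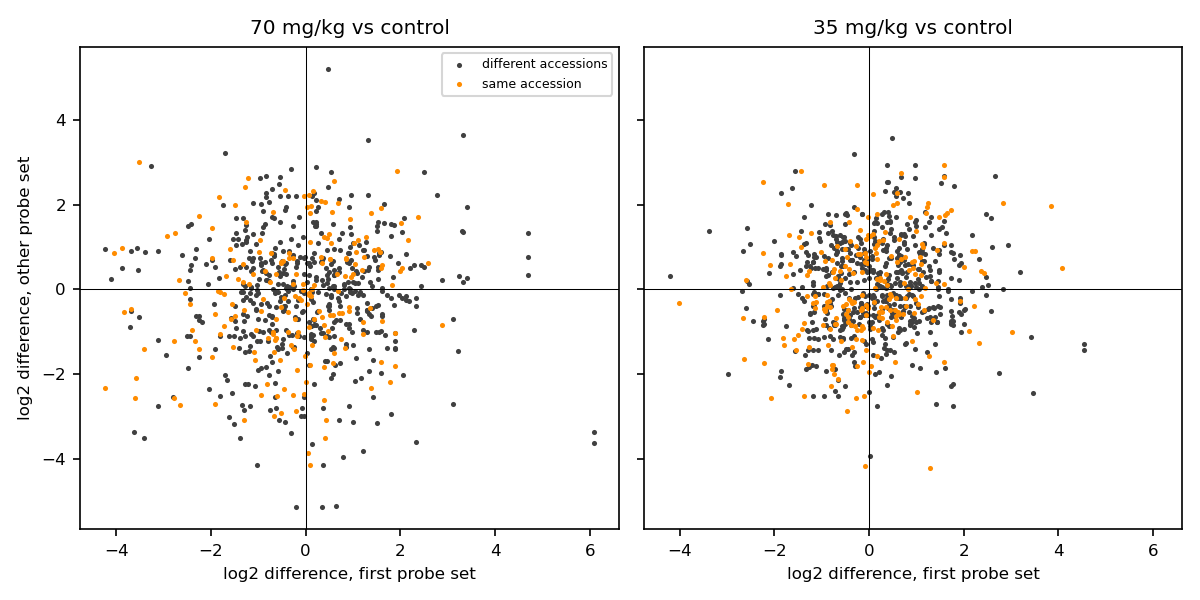
Log2 difference from control of 1 probe set (horizontal axis) against that of another probe set of the same gene (vertical axis), at 70 mg/kg and at 35 mg/kg, with pairs from the same sequence accession in orange. The points form a round cloud, with r = 0.0557 over 730 pairs at 70 mg/kg and 0.0879 over 832 pairs at 35 mg/kg.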

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

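The explanations in this part were tested only after the spike-in values had been seen. The bacterial and phage control transcripts, added already labelled at hybridisation, lie outside the aortic measurements. They were brighter on both treated arrays than on the control array, by a median of 3.81-fold at 35 mg/kg and 28.8-fold at 70 mg/kg over 9 probe sets. Less labelled aortic RNA hybridised relative to the spike-ins is a candidate explanation at 70 mg/kg: it predicts a narrower range of aortic probe sets, and the 95th over the 5th percentile was 5.22 on the log2 scale against 6.58 on the control array. More spike-in added to that array alone predicts the range of the control array, and the difference of -1.36 cannot be set against a spread between arrays of one group, since each group had 1 array. A lower yield of RNA from aortas of treated rats is the biological explanation that the groups allow, and it was not tested.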

How the results depend on the processing

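In this part, the floor at the 75th percentile, the removal of less specific probe sets and the pairs from different accessions were chosen after the results had been seen. Over all alternatives, summary results stayed within the bounds set for them in 122 cases and moved past them in 57. List medians stayed in 776 cases, moved in 58 and, among lists standing apart, changed sign in 5, which were the macrophage list between the doses and the fatty acid oxidation list at 70 mg/kg. Medians of other lists are counted by size alone, and over all lists the sign differed in 147 cases. Named genes stayed in 1565 cases, moved in 52 and, where the gene was at least 2-fold different, changed sign in 21, all from the floor or the choice of probe set. Scaling moved the median of all genes by less than 0.1 and changed the sign of genes below 2-fold, which were Acta2 and Lox at 70 mg/kg (0.13 and -0.55 with the values as deposited) and Lox and Myh11 between the doses (-0.70 and -0.18). With the values as deposited, 1 list stood apart at 70 mg/kg, with a common trimmed mean 1, and after quantile normalization 1 at 35 mg/kg and 0 between the doses. With 3-fold in place of 2-fold, which by its construction leaves fewer genes, 213 genes were higher and 300 lower at 70 mg/kg, 168 and 161 at 35 mg/kg, and 145 and 224 between the doses. A list count was not computed at 3-fold or for each probe set by itself, and a list with fewer than 5 measured genes gave no percentile. No paired analysis was possible because each group had 1 array.

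Lower floors let in more genes and higher floors fewer, by construction, and for the other differences below the cause was not tested. At the 25th percentile floor 590 genes were higher and 789 lower between the doses, 330 were lower at both doses, the doses correlated with r = 0.541, the percent with the 35 mg/kg value between the others was 59.0 and 1 list stood apart at 35 mg/kg. There Cbr1 (0.32) and Cyp2c13 (-0.0087) had the other sign at 70 mg/kg, as did Gpam (0.28), Lss (-0.25) and Myh11 (0.45) at 35 mg/kg and the macrophage list (-0.54) between the doses. At the 5th percentile floor 1074 genes were higher and 1165 lower at 70 mg/kg, 852 and 982 at 35 mg/kg, and 1017 and 1026 between the doses. Higher at both doses were 449 and lower at both 524, r between the doses was 0.516 and the percent between was 56.6. Lists standing apart numbered 7 at 70 mg/kg and 1 between the doses, and the correlation between probe sets was 0.0749 at 70 mg/kg, 0.0551 at 35 mg/kg and 0.0343 between the doses. At this floor Acat2 (-0.39), Cbr1 (0.32), Cyp2c13 (-0.0087) and Hlf (-0.89) had the other sign at 70 mg/kg, Gpam (1.09), Lss (-0.91), Nppa (-0.29) and Myh7 (1.0) at 35 mg/kg, and the macrophage list (-0.047) between the doses.

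At the 55th percentile floor 256 genes were higher and 333 lower at 70 mg/kg, 268 and 282 at 35 mg/kg, and 194 and 316 between the doses, with 97 higher and 115 lower at both doses and 65.3% with the 35 mg/kg value between. There 1 list stood apart at 70 mg/kg and 1 between the doses, the fatty acid oxidation median was 0.0048 and Cd14 lay at -0.047 between the doses. At the 75th percentile floor 71 genes were higher and 159 lower at 70 mg/kg, 132 and 137 at 35 mg/kg, and 47 and 163 between the doses. Lists standing apart numbered 1 at 70 mg/kg, 0 at 35 mg/kg and 1 between the doses, and the correlation between probe sets was 0.237, 0.216 and 0.181. At this floor the fatty acid oxidation median was 0.059, and Cd14 (-0.047) and Gstm1 (-0.55) had the other sign between the doses. With the brightest probe set per gene, 0 lists stood apart at 35 mg/kg and 1 between the doses. Tpm1 then had the other sign at both doses (6.09 and 4.53), as did Slc2a4 (1.38) at 35 mg/kg and Cd14 (-0.047), Gstm1 (-0.55) and the macrophage list (-0.047) between the doses. With pairs from different accessions only, the correlation between probe sets at 35 mg/kg was 0.0341.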

Other observations

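In this part, the tests of weak signal, of allylamine dose, of perivascular fat and of the number of lists were chosen after the results had been seen, as were the pairs from different accessions, at every floor, and the floors at the 65th, 75th and 85th percentile. Immune and vascular cell genes at 70 mg/kg had list medians within the random range. Interferon response and antigen presentation had a median of 0.16 (76.0th percentile), with 3 of 14 genes at least 2-fold higher and 0 lower. These were the peptide transporter Tap2 (2.06), the interferon regulatory factor Irf1 (1.90) and the antiviral GTPase Mx1 (1.76), with Psme1 at 0.97. Mx1 was also higher at 35 mg/kg, by 2.05. Cytokines, chemokines and adhesion had a median of -0.06, which was above 0 with the values as deposited (0.06). In this list Il4r (2.13), the leukocyte adhesion molecule Vcam1 (2.12) and the interferon-induced chemokine Cxcl10 (1.93) were higher and the chemokine receptor Cxcr4 lower, at -2.19 on 2 probe sets (-3.07 to -1.30). At 35 mg/kg Vcam1 was at 2.02 and Cxcr4 at -2.32 on 2 probe sets (-2.57 to -2.06). The endothelial list had a median of -0.56 (12.9th percentile). The nitric oxide synthase Nos3 was at 1.52 (3 probe sets, -0.36 to 1.86), the growth factor receptor Flt1 at -1.20, Ace at -1.16 and thrombomodulin (Thbd) at -1.13.

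Apoptosis genes had a median of -0.82 at 70 mg/kg (4.07th percentile), with 6 of 13 genes at least 2-fold lower and 2 higher. Those lower included Mdm2, the stress pseudokinase Trib3 (-2.19, 2 probe sets at -3.84 and -0.54), the caspase activator Diablo (-2.15) and Bad (-1.78). Cardiac muscle markers had a median of 0.47 (91.1st percentile) at 70 mg/kg and 0.52 (91.3rd percentile) at 35 mg/kg, with Nppa at 2.97 and 3.18. The cardiac myosin Myh7 was at -1.51 at 35 mg/kg, but 1.0 with a floor at the 5th percentile, with which Nppa was at -0.29. At 70 mg/kg Myl4 was at 2.69 and Csrp3 at -2.54. The smooth muscle phenotypic modulation list had a median of -0.22 at 70 mg/kg, which was 0.01 after quantile normalization. In this list the keratin Krt18 was at 2.30, Tnc at 1.35 and cyclin D1 (Ccnd1) at -1.62. At 35 mg/kg, matrix proteases and inhibitors had a median of 0.57 (96.7th percentile) with Adam17 at 1.38. Mast cell markers there had a median of 0.88 (97.2nd percentile) with Tpsb2 at 1.34 and Tpsab1 at -1.39. Nerve and Schwann cell markers had a median of 0.56 (95.5th percentile) with the synaptic protein Snap25 at 1.5 on 2 probe sets (1.20 to 1.81).

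Of the pattern formed by many 2-fold differences and low agreement between probe sets of one gene, names wholly out of register with the values are argued against. Levels of probe sets of one gene correlated on every array with r of at least 0.103, above the upper bound of random pairings (at most 0.0357). Pairs from different accessions gave at least 0.0839, above the highest of 100 shifts of the names (0.0566). These correlations are low, and names out of register for part of the probe sets were not tested. Measurement error of single probe sets may account for many of the differences and was left undecided once other floors had been seen: at 70 mg/kg r was 0.0557, within random, but at 4 of 7 floors it lay above random, and at 35 mg/kg r of 0.0879 passed the bound set beforehand and lay above random at 6 of 7. That bound takes no account of probe sets from one accession, which may share probes (235 pairs at 35 mg/kg, r = 0.20), whereas pairs from different accessions lay above random at 4 of 7 floors at 70 mg/kg and at 0 of 7 at 35 mg/kg (0.0341 over 597 pairs at the main floor). The 7 floors are nested subsets of the same pairs and not separate checks, and some of the 4 rested on few pairs or a near tie. At 70 mg/kg the SD between probe sets of one gene (1.40) was as large as that over all named probe sets measured (1.37). Simulated error of this size took 37.2% of unchanged genes past the 2-fold rule, against 42.9% of the genes measured at 70 mg/kg. Error set as wide as the spread of all differences gives a share near the observed one by construction, so this comparison cannot decide. The simulation also treated all of the spread between probe sets as error. Which genes measurement error covers was not settled. Weak aortic signal cannot be told apart from this, since agreement among the brightest of 3 intensity classes at 70 mg/kg was 0.00879 over 133 pairs, below the 0.220 over 60 pairs of the dimmest class, but 0.237 over 82 pairs above the 75th percentile floor (random pairings up to 0.209), and lists of abundant transcripts stood above random levels in 1 of 9 list and array combinations. An allylamine dose effect stays open as well: of the 944 genes at least 2-fold from control at 70 mg/kg, 62.1% had the 35 mg/kg value between the others, against 57.4% simulated (53.7% to 61.1%), without agreement between probe sets beyond random at the main floor at 70 mg/kg. The simulation gave all 3 arrays the same error, while the SD between probe sets of one gene was 1.40 at 70 mg/kg and 1.08 at 35 mg/kg. This share therefore cannot decide the question.

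The lower fatty acid oxidation genes at 70 mg/kg are a second pattern. One of many lists standing apart by chance remains a candidate explanation, since 3 of 33 lists stood apart where shuffled genes gave up to 4 at the 95th percentile, and 6.8% of 1000 shuffles held a list as far below. Less perivascular fat on the 70 mg/kg array predicts lower fat markers. White and pan-adipocyte markers outside the list had a median of 0.53 (91.1st percentile), 1.56 above the list. Brown adipocyte markers outside it had a median of 0.46 (73.2nd percentile), 1.5 above it. Both medians go against less fat, but the members were divided. Of the 8 white and pan-adipocyte markers, 1 was at least 2-fold higher (Aqp7, 1.51) and 2 were lower. The lower 2 were the lipase Lipe (-1.31, 2 probe sets at -1.52 and -1.11) and Slc2a4 (-1.25, 2 probe sets at -3.39 and 0.89). Of 6 brown adipocyte markers, 3 were at least 2-fold higher and 1 was lower. The resampled interval of the difference of 1.56, -0.58 to 2.64 over 8 markers, included 0, a condition added after the median had been seen. Less fat therefore cannot be told apart from the other explanations. A response to allylamine in fatty acid oxidation stays open and was not tested further; the list's median at 35 mg/kg was -0.15 (30.4th percentile).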
